A study of Mus musculus with 32 samples.

How the data were processed

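The series holds 32 samples of WT and H1-TKO mouse embryonic stem cells. Values came from 6 MapR libraries (2 RNH and 1 MNase-only library per genotype) and, through 1 table for the whole series, from 6 cheRNA samples (3 per genotype). The samples of the other assays (RNA polymerase II ChIP, MNase digestion, TT-seq and ChrMeRIP with their inputs) were not analysed here. Groups and replicate numbers follow the sample labels, and the labels do not say how replicates relate to cultures or whether a TKO replicate pairs with the WT replicate of the same number.

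Per the submitters' processing notes, TopHat2, BWA, SAMtools, bedtools, DESeq2 and MACS2 were used with the mouse build mm10; their versions and the step each served are not given in the sources used here. The cheRNA file is the authors' deposited table of 5723 transcripts with the log2 fold change between genotypes as the authors computed it. It has no p-value and no value per sample. All its absolute log2 values are at least 1.00, so unchanged transcripts are not in it. The direction of the fold change is not stated. Transcripts of the 3 H1 genes known as background to be deleted were positive, so all values were multiplied by -1 to read as TKO over WT, which is an inference. Each peak list was deposited by the authors for 1 library, in the layout of MACS2, and holds the fold enrichment of each peak over the local background (a ratio). The authors' lists also give -log10 p and -log10 q of each peak, and a score that equals the whole part of 10 times the -log10 q. The control library and options of peak calling are not given in the sources used here. No reads were counted, so depth is unknown and no interval for counting error is given.

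Transcript classes were read from the prefixes of the deposited transcript names and tested by position against GENCODE release M21. Of the 5723 transcripts, 5596 carried a gene name found there. Gene and 5′ transcripts lay on the strand of the named gene in 100% of cases, and antisense transcripts within genes and bidirectional transcripts in 0%. Intergenic transcripts carry the name of a gene that may lie far away or not be the nearest, and 20.7% of them overlap that gene on either strand. Of all intergenic transcripts, 46.1% lay outside every annotated gene, and 11.4% lay over a coding gene on the same strand. Of 5′ transcripts with a name found, 65.9% overlapped the named gene. The classes are therefore the authors' names and not strict positions.

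Peaks were set against transcripts, genes and each other by overlaps of at least 1 bp. Peaks and regions that overlapped an MNase-only control peak of either genotype were removed, except from peak numbers and from the shares of chromosomes. A shared region is the span of overlapping peaks from both replicates of a genotype, and a genotype-only region is a shared region that meets no peak of the other genotype. Promoters are annotated transcription starts with 1 kb on both sides; the remaining peaks were assigned to exons, introns or intergenic sequence. Each library's peaks were shuffled 1000 times within chromosomes, and observed overlaps were divided by the shuffled mean. Genotypes were compared by two-sided exact permutation tests of 2 against 2 libraries, transcripts and regions by two-sided Fisher's exact tests. Chromosomes were tested by Fisher's exact test with Benjamini-Hochberg adjustment over 21 chromosomes.

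Gene lists covered H1 genes, pluripotency, imprinted, nuclear long non-coding RNA, 2-cell-stage and germline genes, the m6A pathway, nuclear RNA decay, R-loop processing, core histones, snoRNA host and small nuclear RNA genes, ribosomal protein and housekeeping genes, p53 targets, and markers of endoderm, mesoderm, neuroectoderm and fibroblasts. A member counted when its gene body overlapped a shared region, or a listed transcript on its own strand. Each count was compared with 10000 random lists matched on gene length in 10 groups, drawn from 37739 genes, and p-values were adjusted by Benjamini-Hochberg over 68 tests at 0.05. The lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule names the deleted H1 genes, the 10 highest and 10 lowest transcripts, the 10 genotype-only regions per direction with the highest smaller fold enrichment, the 4 list members per direction with the largest fold, and the 10 highest transcripts with a TKO-only region. Some items that the rule or the lists would name are not reported here. Named in addition, after their values were seen, were list members with transcripts of other classes or with shared regions, and Rab11fip5 among lower transcripts. The tests by class and by chromosome, and the settings without chromosome 11, without chromosomes 1, 11 and 14, or without chromosome 14 from 90 to 100 Mb, were also added after the data had been seen.

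Alternatives were a stricter peak threshold (-log10 q of at least 5), equal list lengths, leaving out each RNH library, a replicate block, overlap of 50%, keeping control peaks, shuffling within gene bodies, promoters of 2 kb, transcripts of at least 1 kb, merged transcripts, gene bodies with 2 kb upstream and peaks in either replicate. Alternatives used 100 shuffles. The methods were tested on simulated data. Overlap counts had 0 mismatches with a direct count over 600 intervals. Planted folds of 1, 2 and 3 were recovered as 0.993 ± 0.0735, 2.03 ± 0.15 and 3.06 ± 0.244 (SD over 10 simulated libraries each). Of 1360 tests of random lists, 0 were called. A planted list was called in 20 of 20 runs, but in every run it held 7 genes with a higher transcript among 23. These are the counts of the germline list, so the runs show only that such a count passes. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.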

Results

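The series compared wild-type (WT) mouse embryonic stem cells with H1-TKO cells, a line that lacks 3 genes of the linker histone H1, the protein that binds DNA where it enters and leaves the nucleosome. Its title asks how H1 governs the turnover of non-coding RNA on chromatin. Of the 32 samples, those analysed here were 6 cheRNA samples and 6 MapR libraries. cheRNA is RNA that stays with the insoluble chromatin pellet after nuclei are extracted with urea and detergent. It was sequenced from 3 samples per genotype with a stranded library kit after removal of ribosomal RNA. The cheRNA data are represented by the authors' deposited table of 5723 transcripts that differed between the genotypes, which holds no value per sample. MapR uses a fusion of inactive RNase H with micrococcal nuclease (RNH) to release DNA near R-loops, which are RNA-DNA hybrids with a displaced DNA strand. Each genotype had 2 RNH libraries and 1 control library made with the nuclease alone (MNase only), and the authors deposited a peak list for each of these 6 libraries. Read depth is unknown, because the lists hold peaks and not reads. No label says whether replicates came from separate cultures, so p-values of tests between libraries measure only the spread between these samples, which may be technical. All other p-values take transcripts, regions, genes or positions as units and measure no spread between samples.

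In the authors' deposited table the gene transcripts of Hist1h1d, Hist1h1e and Hist1h1c had log2 TKO over WT values of -5.02, -4.83 and -3.61, or 32.5-fold, 28.5-fold and 12.2-fold less RNA on chromatin in TKO cells. That these are the deleted genes is background knowledge, since the labels say only that the line is a knockout of H1. The file does not state which genotype is the numerator of its fold change, and the sign used throughout was set from these 3 genes, so that their lower level is not independent evidence. The other H1 genes with a listed gene transcript all lay in the opposite direction. Hist1h1t, the testis-specific H1 gene, was 11.5-fold higher in TKO, H1f0, the replication-independent H1 of non-dividing cells, 6.14-fold, H1fx 2.46-fold and Hist1h1b 2.01-fold. An antisense transcript across Hist1h1c was also higher, by 7.93-fold, as was a sense transcript on the 5′ side of Hist1h1d, by 3.10-fold. Among the 9 H1 genes, 6 overlapped a transcript higher in TKO on their own strand, against 2.61% in 10000 random lists of genes of matched length (permutation test, adjusted p = 0.0045), and the 3 deleted genes overlapped a lower one, a direction fixed by the choice of sign. Of the 6, Hist1h1d was counted for the transcript on its 5′ side and Hist1h1e for a transcript named for its neighbour Hist1h2be. MapR peaks lay on all of the deleted genes in at least 1 library of each genotype. These genes therefore do not check the MapR labels, as the deleted parts are not given in the sources used here.

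**Figure D1:**
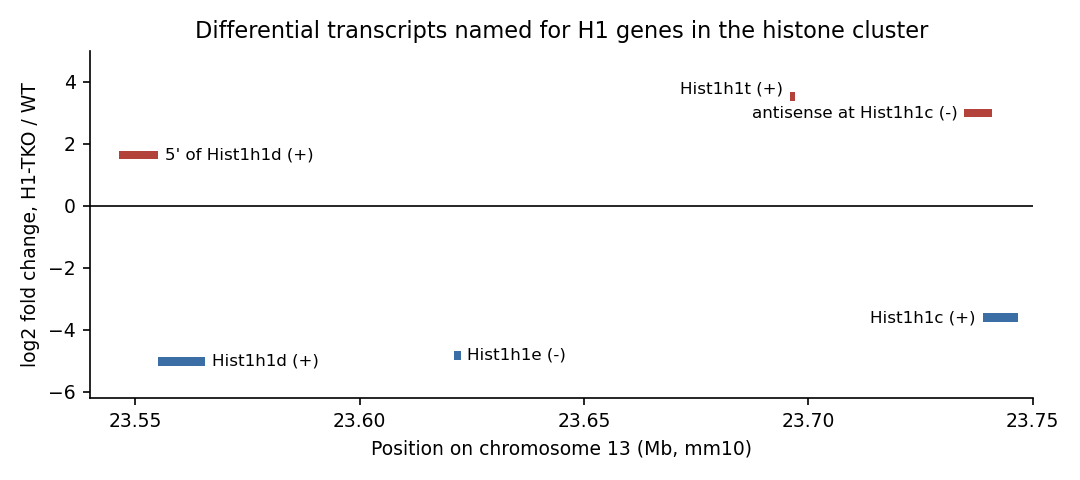
Differential cheRNA transcripts named for H1 genes in the histone cluster of chromosome 13 (mm10). The horizontal axis is the position in Mb, the vertical axis the authors' log2 fold change turned to H1-TKO over WT, each bar spans 1 transcript, and the strand is in parentheses. The transcripts of Hist1h1d, Hist1h1e and Hist1h1c lie at -5.02, -4.83 and -3.61, while Hist1h1t lies at 3.52 and the antisense transcript at Hist1h1c at 2.99.

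The next comparison asked which chromatin-bound transcripts were more or less abundant without H1. The authors' deposited table listed 3437 transcripts higher in TKO (60.1%) and 2286 lower (39.9%), each changed at least 2.00-fold. The 2904 transcripts that carried a gene's own name leaned downward, with 1307 higher (45.0%) and 1597 lower. The other classes leaned upward. Of the 1937 intergenic transcripts 1434 (74.0%) were higher, as were 323 of the 373 antisense transcripts within genes (86.6%), 158 of the 185 bidirectional transcripts that start near a gene on the opposite strand (85.4%), and 215 of the 324 on the 5′ side of a gene (66.4%). Against gene transcripts, the odds of being higher were 3.48 times larger for intergenic (two-sided Fisher's exact test, p = 4.1e-91), 7.89 times for antisense (p = 1.9e-56), 7.15 times for bidirectional (p = 2.0e-28) and 2.41 times for 5′ transcripts (p = 3.0e-13). These tests take transcripts as units, which are not replicates, and cover only transcripts the authors listed. Classes follow the authors' names: 46.1% of intergenic transcripts lay outside all annotated genes, and 67.6% of 5′ transcripts lay over a coding gene on their strand. The median higher intergenic transcript had a log2 value of 2.63 and a width of 7208 bp, while the median lower gene transcript had -1.66 and 22364 bp. The gene transcripts belonged to 2014 genes, of which 331 had several listed transcripts. In 325 of those all transcripts went one way, and 6 genes had both directions.

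**Figure D2:**
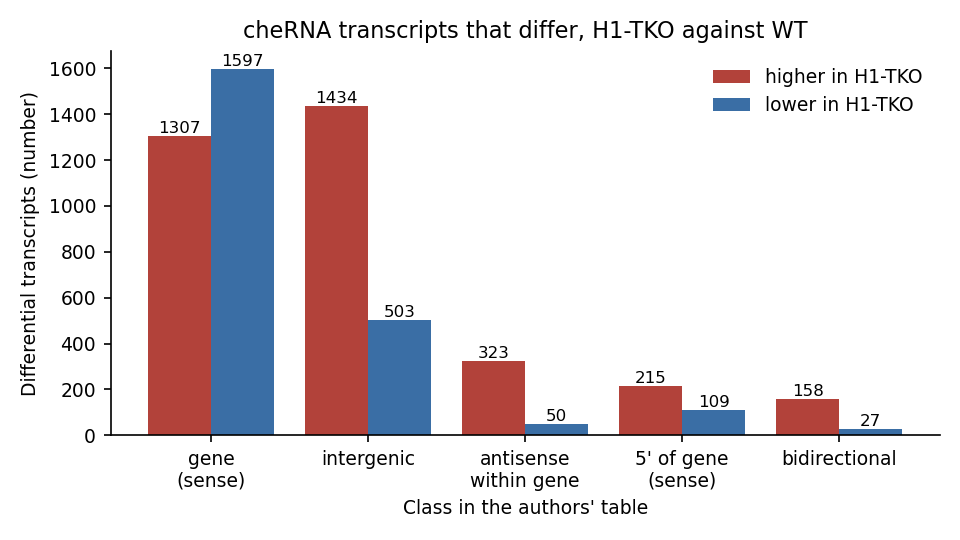
Number of transcripts in the authors' deposited table that were higher (red) or lower (blue) in H1-TKO than in WT cells, by class of transcript; each bar is a count with no error. Gene transcripts split 1307 to 1597, while intergenic transcripts split 1434 to 503.

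The largest values of the authors' deposited table belonged mostly to classes other than gene transcripts. The 10 highest were led by an intergenic transcript of 239774 bp that runs antisense across Tfec, a transcription factor gene of chromosome 6 (16681000 to 16920773), with a log2 TKO over WT of 9.48. An intergenic transcript 12568 bp from Znrf3, which encodes a ubiquitin ligase of Wnt receptors, followed at 9.43 (chromosome 11, 5457416 to 5464193), and one on the 5′ side of Spink13 at 9.28 (chromosome 18, 62741389 to 62749715). Intergenic transcripts named for C1qtnf1 (8.83), Pdgfb (8.75), Slit3 (8.48), Nkain3 (8.26) and Foxd3 (8.17), a 5′ transcript of Calu (8.27) and the gene transcript of 2300002M23Rik (8.57) completed the 10. Foxd3 encodes a transcription factor of pluripotent and neural crest cells, and the transcript named for it lay 66250 bp away. At the low end, Trpv5, an epithelial calcium channel, had a log2 value of -6.77 (chromosome 6, 41669647 to 41670975), Msln, the surface protein mesothelin, -6.43, Trim29 -6.27 and Cemip, a hyaluronan-binding protein, -5.85. Among the lowest were also an antisense transcript in Rnf11 (-6.53), 5′ transcripts of Dync1i1 (-6.48) and St7 (-5.89), and intergenic transcripts named for Adgrl2 (-5.82) and Cntn5 (-5.77). The table gives no error for these folds, and a fold this large can rest on few reads in 1 genotype, which could not be checked without counts.

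Genes of known function were grouped into 17 lists fixed before the data were examined, and each list was set against random lists of matched gene length. Germline genes were enriched among higher transcripts. Of 23 found, 7 overlapped a transcript higher in TKO (30.4% against 5.24% in random lists, permutation test, adjusted p = 0.0045 over 68 tests) and 0 a lower one. In the authors' deposited table Smc1b, a meiotic cohesin gene, was 10.0-fold higher, Stra8, which starts meiosis, 7.16-fold, the testis tubulin gene Tuba3a 6.41-fold and Hormad1, a protein of meiotic chromosome axes, 3.92-fold. Without chromosome 11 the count was 6 of 22 (permutation test, adjusted p = 0.020), the highest of 4 alternatives. The lowest, 0.0019, came with peaks in either replicate, a setting that changes this test through the adjustment alone. Pluripotency genes did not pass in either direction (3 of 29 in each, permutation test, adjusted p = 0.96 for higher and 0.73 for lower). Their listed members went both ways, with Dppa3 at a log2 TKO over WT of 3.01 and Gdf3 at 1.29, and Klf5 at -2.23, Myc at -1.95 and Dnmt3l at -1.07. Klf5 lies on chromosome 14 between 90 and 100 Mb, where WT libraries held 252 and 169 RNH peaks and TKO libraries 36 and 7, and all 8 listed transcripts were lower. Transcripts of the other classes named for a pluripotency gene were higher in 22 cases and lower in 9, where 75.6% of all such transcripts were higher, and this was not tested. They included 3 near Sox2 with log2 values of 5.67, 3.61 and 1.74, and 3 near Nanog with 3.56, 2.23 and 1.35. The pair near Myc was lower.

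Imprinted genes were listed on both sides, 4 of 32 higher and 6 of 32 lower (permutation test, adjusted p = 0.73 and 0.15). In the authors' deposited table Peg12 was 6.59-fold higher, whereas Kcnq1, a potassium channel gene with 7 listed transcripts, was up to 7.16-fold lower, Peg10 5.74-fold and the zinc finger gene Plagl1 3.38-fold. Usp29 had transcripts in both directions, with log2 TKO over WT values of 3.35 and -1.35. The nuclear long non-coding RNA genes had 2 of 28 members overlapping a transcript in each direction (permutation test, adjusted p = 1 for both), Lncenc1 and Rmst on the higher side and Ftx and Pvt1 on the lower. Of 23 genes of the m6A pathway, which writes, reads and erases methylated adenosine in RNA, 0 were higher and 1, Igf2bp3, was 2.11-fold lower (permutation test, adjusted p = 1). Transcripts of the other classes named for this pathway were higher in 7 of 8 cases, with no test and against 75.6% of all such transcripts, among them an antisense transcript within Fto (25.0-fold) and intergenic transcripts on chromosome 11 named for Mettl16 (46.8-fold) and Igf2bp1 (65.6-fold). Among 23 nuclear RNA decay genes, Dis3, a nuclease of the RNA exosome, was the one with a listed gene transcript, 5.25-fold lower (permutation test, adjusted p = 1), and lies in the same part of chromosome 14 as Klf5. Genes of R-loop processing (2 of 22 higher), 2-cell-stage genes (1 of 16 higher), p53 targets (1 of 18 in each direction), housekeeping genes (1 of 20 higher), core histones and snoRNA host genes (0 in either direction) did not pass, with an adjusted p of 1 for each in both directions (permutation tests).

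Markers of other cell types were measured beside these groups. Of 13 neuroectoderm markers, 4 were higher, namely the neuronal tubulin gene Tubb3 (6.81-fold), Otx2 (3.83-fold), Pax6 (2.88-fold) and Ncam1 (2.17-fold), and Olig2 was lower (2.26-fold). The higher side missed the threshold (permutation test, adjusted p = 0.057) and passed it without chromosome 11 and with peaks in either replicate (adjusted p = 0.037 in both). The latter setting changes this test through the adjustment alone. The adjusted p ranged from 0.037 to 0.13 over 4 alternatives. Of 15 endoderm markers, 3 were lower in the authors' deposited table, the basement membrane collagens Col4a1 (2.55-fold) and Col4a2 (3.83-fold) and the adaptor Dab2 (3.50-fold), with an adjusted p of 0.45 (permutation test), and Sparc was 2.08-fold higher. Mesoderm markers had 1 of 13 higher and 2 of 13 lower (permutation test, adjusted p = 1 and 0.39), with Gsc at a log2 value of 3.03 and Bmp4 at -2.86. Of 13 fibroblast markers, 1 was higher, the intermediate filament gene Vim (4.76-fold, permutation test, adjusted p = 1).

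The direction of change also differed between chromosomes. On chromosome 11, 478 of 541 listed transcripts (88.4%) were higher in TKO, an odds ratio of 5.70 against the other chromosomes (Fisher's exact test, adjusted p = 7.1e-51 over 21 chromosomes), and gene transcripts took part, with 184 of 229 higher. Chromosome 9 stood at the other end, with 233 of 340 transcripts lower (Fisher's exact test, adjusted p = 5.6e-27). In all, 4 chromosomes had a larger and 7 a smaller share of higher transcripts than the rest at an adjusted p under 0.05. Transcripts, which are not replicates, were the units of these tests. MapR shifted as well. Chromosome 11 held 8.48% and 10.5% of RNH peaks in TKO replicates 1 and 2 against 6.58% and 6.06% in WT, and chromosome 14 held 3.94% and 3.59% against 4.99% and 6.16%. On chromosome 14 most of the shift lay in the bin from 90 to 100 Mb, with 36 and 7 TKO peaks against 252 and 169 WT peaks, and the rest of the chromosome held 3.81% and 3.49% of peaks in TKO against 3.91% and 3.69% in WT. Within that rest, the bin from 100000001 leaned toward WT (46 and 9 TKO against 56 and 31 WT peaks). Those from 110000001 (51 and 8 against 18 and 5) and 120000001 (58 and 13 against 29 and 10) leaned toward TKO. Chromosome 1 had log2 TKO over WT shares of -0.23 and -0.63 for the replicates, whereas chromosome 9 had -0.10 and 0.03. Without chromosome 11, 57.1% of the listed transcripts were higher, and the odds ratio of intergenic against gene transcripts was 3.53.

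**Figure D3:**
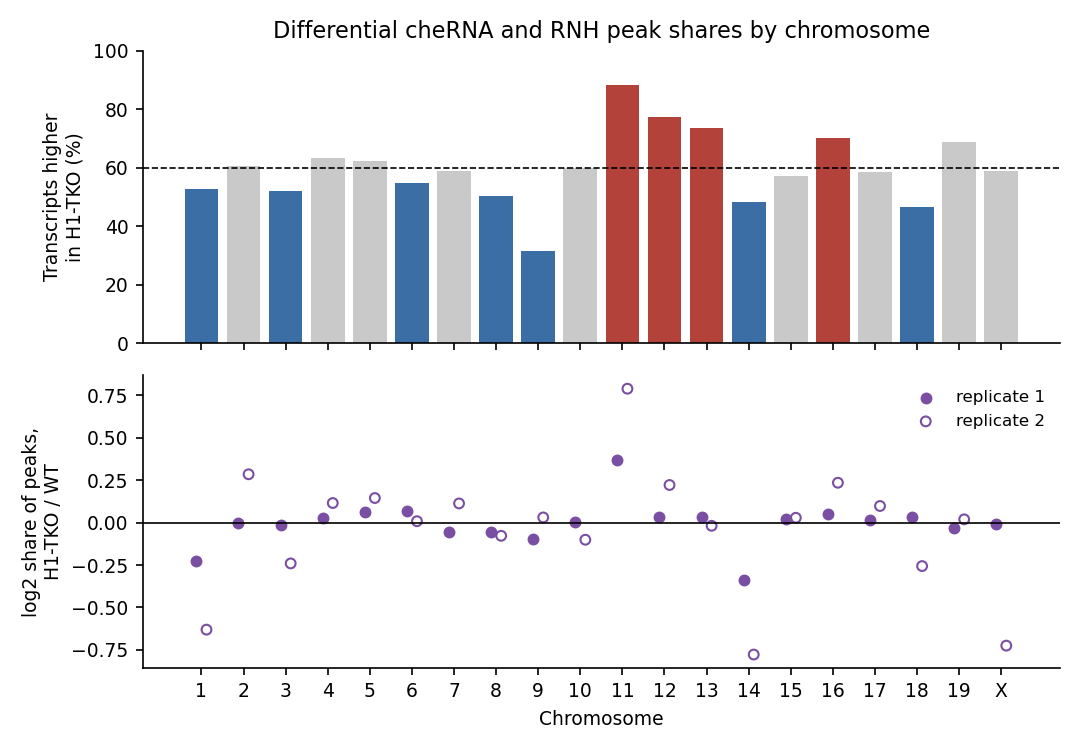
Top, percent of differential cheRNA transcripts that were higher in H1-TKO, per chromosome; coloured bars have an adjusted Fisher p under 0.05 (red above, blue below the other chromosomes) and the dashed line is the 60.1% of all transcripts. Bottom, log2 ratio of each chromosome's share of RNH peaks, H1-TKO over WT, with a filled point for replicate 1 and an open point for replicate 2. Chromosome 11 lies at 88.4% in the top panel and at 0.37 and 0.79 in the bottom panel; chromosome Y is not drawn.

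The MapR peak lists were then compared with their controls and between genotypes. RNH libraries gave many more peaks than the nuclease alone. TKO replicates had 25392 and 6458 peaks and WT replicates 22336 and 6612, against 582 in the TKO and 568 in the WT control, a geometric mean ratio of 21.7. The ratio was 43.6 and 39.3 for replicate 1 of TKO and WT and 11.1 and 11.6 for replicate 2, and its geometric mean was 13.7 with the stricter peak threshold. Between 1.79% and 6.94% of RNH peaks lay in a control peak, a share that the short control lists keep low. In the other direction, 61.4% to 75.6% of the peaks of a control lay in a peak of a given RNH library. The number of peaks did not differ between genotypes beyond the spread of replicates (log2 TKO over WT 0.08, two-sided exact permutation test, p = 1, where 0.33 is the smallest p that 2 against 2 libraries allow). Replicate 1 had 3.93 times as many peaks as replicate 2 in TKO and 3.38 times in WT. Leaving out TKO replicate 1 turned the log2 value to -0.91, and leaving out WT replicate 2 turned it to -0.80. It was 1.06 without TKO replicate 2, 0.95 without WT replicate 1 and 0.03 without chromosome 11.

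**Figure D4:**
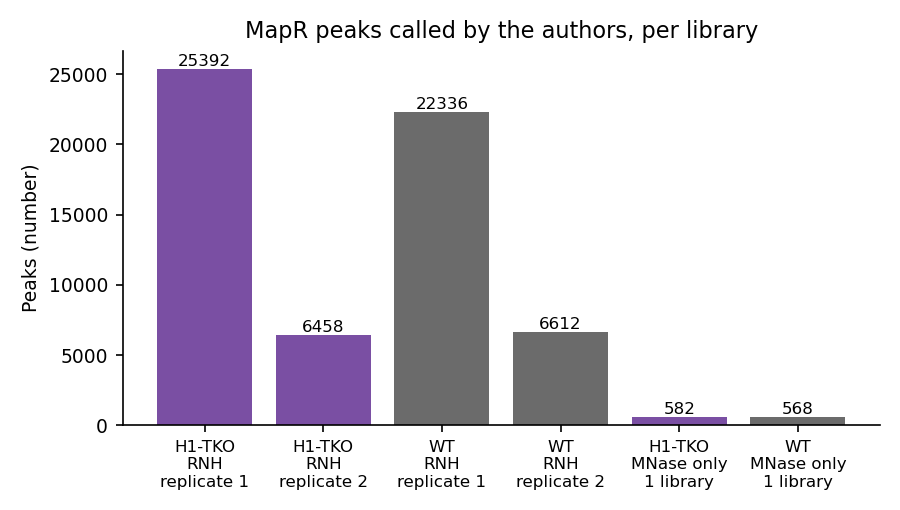
Peaks deposited for each MapR library; the vertical axis is the number of peaks, purple bars are H1-TKO and grey bars WT, and a bar is 1 library with no error. The 4 RNH libraries lie between 6458 and 25392 peaks and the control libraries at 582 and 568.

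RNH peaks were enriched at promoters in both genotypes. Within 1 kb of an annotated transcription start lay 51.5% ± 2.57 (SD, n = 2) of TKO and 45.5% ± 5.35 (SD, n = 2) of WT peaks, 5.91 to 7.62 times the share of shuffled peaks in each library. The genotypes differed by 6.03 percentage points (exact permutation test, p = 0.33, the smallest possible), by 2.25 without WT replicate 2, by 9.82 without WT replicate 1 and by 3.10 with the stricter peak threshold. Intergenic peaks made up 26.5% ± 2.27 in TKO and 31.6% ± 3.48 in WT (n = 2 each, exact permutation p = 0.33). Both replicates shared 3662 regions in TKO and 3524 in WT, and 1550 TKO regions met a WT region, 76.8% of them at promoters. Regions that did not meet cannot be read as genotype differences, as replicates of a genotype overlapped little better. Of TKO replicate 2 peaks, 65.0% met replicate 1 of TKO and 65.9% that of WT. Of WT replicate 2 peaks, 60.7% met replicate 1 of WT and 58.6% that of TKO.

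Shared regions fell on histone and small RNA genes more often than on random genes of matched length. Among 20 core histone genes found, 4 held a TKO region (Hist1h4b, Hist1h4h, Hist2h3c1 and Hist2h2bb; permutation test, adjusted p = 0.031) and 5 a WT region, the same 4 and Hist1h2bc (adjusted p = 0.0054). Among 17 snoRNA host and small nuclear RNA genes, 5 held a TKO region, namely Gas5, the RNase P RNA gene Rpph1, the RNase MRP RNA gene Rmrp, the U2 RNA gene Rnu2-10 and the U12 RNA gene Rnu12 (permutation test, adjusted p = 0.0045). In WT 5 did, with Scarna2 in place of Rnu12 (permutation test, adjusted p = 0.0054). Ribosomal protein and housekeeping genes passed in TKO, with 6 of 20 (permutation test, adjusted p = 0.031), namely Eef1a1, Eef2, Hspa8, Npm1, Ncl and Pgk1, none of which encodes a ribosomal protein. In WT the list missed with 4 of 20 (permutation test, adjusted p = 0.30), ranging from 0.0019 to 0.61 over 4 alternatives, and the difference between genotypes was not tested. Over 4 alternatives the adjusted p of core histones in TKO ranged from 0.0019 to 0.058, the highest with 2 kb of upstream sequence. That of housekeeping genes in TKO ranged from 0.0019 to 0.28 and was 0.074 without chromosome 11. The small RNA genes missed the threshold in both genotypes without chromosomes 1, 11 and 14, with 2 of 12 (permutation test, adjusted p = 0.41 in TKO and 0.38 in WT, the highest over the alternatives). The lists are small and expression could not be matched. Pluripotency genes held 1 TKO and 6 WT regions among 29 (permutation test, adjusted p = 1 and 0.39), and no other list passed in either genotype with regions of both replicates. With peaks in either replicate, housekeeping and H1 genes passed in WT, nuclear RNA decay genes in TKO and the m6A pathway in both. Over the alternatives, the adjusted p (permutation tests) ranged from 0.0091 to 1 for H1 genes in WT, from 0.0074 to 1 for nuclear RNA decay in TKO, and for the m6A pathway from 0.022 to 1 in TKO and from 0.0030 to 0.95 in WT.

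Regions found in both replicates of one genotype and in neither of the other numbered 432 for TKO and 447 for WT, after removal of those in control peaks. Splitting the 4 libraries in the crossed way, TKO replicate 1 with WT replicate 2 against the others, gave 362 and 376, and splitting them by replicate number gave 9179 and 165. When a library was left out, the whole list of the library left stood in for the regions of both replicates, so both counts changed in meaning. Without TKO replicate 1 they were 1861 and 1783, without TKO replicate 2 the TKO-only count was 10239, without WT replicate 1 they were 2035 and 2370, and without WT replicate 2 the WT-only count was 7214. The stricter peak threshold gave 147 and 214, and equal list lengths gave 263 TKO-only regions. Ranked by the smaller of the authors' fold enrichments in the replicates, the TKO-only regions were led by one 346498 bp from Pabpc4l (chromosome 3, 46095282 to 46095698, intergenic, 5.77-fold), one in an intron of Nxpe4 (chromosome 9, 48217568 to 48217906, 5.70-fold) and one 75514 bp from Nova1 (chromosome 12, 46618648 to 46619002, 5.29-fold). Others covered the promoters of Exosc2, a subunit of the RNA exosome (chromosome 2, 31670575 to 31671050, 5.22-fold), and Haus6, a subunit of the augmin complex of the spindle (chromosome 4, 86611546 to 86612123, 4.99-fold). WT-only regions were led by one 167462 bp from Mid1 (chromosome X, 169517351 to 169517736, 6.06-fold), one at the promoter of the kinase gene Rps6ka6 (chromosome X, 111462882 to 111463790, 5.72-fold) and one 497764 bp from Pcmtd1 (chromosome 1, 7671393 to 7672167, 5.35-fold). Another lay at the promoter of Rab11fip5 (chromosome 6, 85374447 to 85375203, 4.97-fold). Promoters made up 131 of the 432 TKO-only and 112 of the 447 WT-only regions (Fisher's exact test, p = 0.083). By chromosome, 70 of the TKO-only regions lay on chromosome 11 against 15 of the WT-only, and 16 against 74 on chromosome 14, where the bin from 90 to 100 Mb held 0 of the TKO-only and 57 of the WT-only regions.

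MapR peaks were next set against the cheRNA transcripts that changed, and compared with shuffled positions. Transcripts higher in TKO held more RNH peaks than shuffled positions in all 4 libraries, 2.17-fold and 2.55-fold in TKO replicates 1 and 2 and 2.17-fold and 1.83-fold in WT (one-sided permutation p = 0.0010 in each, the smallest that 1000 shuffles allow). Transcripts lower in TKO held 1.46-fold and 1.08-fold in TKO (permutation p = 0.0010 and 0.15) and 1.73-fold and 1.43-fold in WT (p = 0.0010 in both). A shuffle p concerns positions within 1 library, not replicates. Unchanged transcripts are not listed, so these folds cannot tell whether changed transcripts differ from other transcribed sequence. Averaged per genotype, the fold in higher transcripts was 2.36 ± 0.272 in TKO and 2.00 ± 0.239 in WT (SD, n = 2 each), a log2 difference of 0.24 (exact permutation test, p = 0.33), and in lower transcripts 1.27 ± 0.272 against 1.58 ± 0.214, a log2 difference of -0.32 (p = 0.667, exact permutation test). The difference in higher transcripts was 0.11 without WT replicate 2 or TKO replicate 2, 0.13 with the stricter peak threshold and 0.15 when shuffled within gene bodies, and that in lower transcripts -0.10 without TKO replicate 2, -0.17 without WT replicate 1, -0.52 without TKO replicate 1 and -0.66 with the stricter peak threshold. When peaks in genes were shuffled within gene bodies only, the geometric mean over libraries fell to 1.55-fold in higher transcripts and to 0.996-fold in lower ones.

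**Figure D5:**
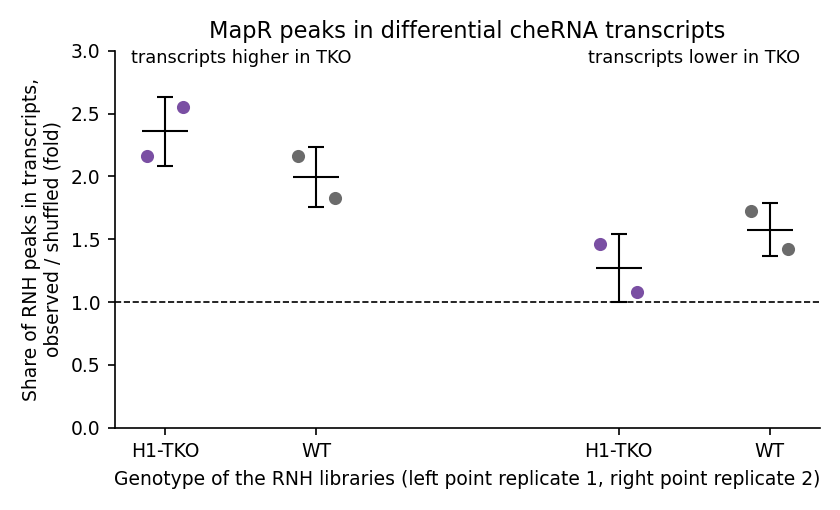
Share of RNH peaks that overlapped cheRNA transcripts higher (left) or lower (right) in H1-TKO, divided by the mean share of shuffled peaks, per library; points are replicates, the horizontal mark and bars are the mean and SD of 2 libraries, and the dashed line is the level of shuffled peaks. In higher transcripts the points lie between 1.83 and 2.55, and in lower transcripts between 1.08 and 1.73.

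Few changed transcripts carried genotype-only regions of one kind, 65 of 3437 higher and 60 of 2286 lower ones. Among these, the region tended to go in the same direction as the transcript. Of the 65 higher transcripts with one kind of region, 47 carried a TKO-only and 18 a WT-only region, and of 60 lower transcripts 20 carried a TKO-only and 40 a WT-only region, an odds ratio of 5.22 (two-sided Fisher's exact test over transcripts, p = 1.5e-05). Higher transcripts with a TKO-only region included an intergenic one named for Pisd (24.5-fold, chromosome 5, 32720718 to 32730460), the gene transcript of Slit3, an axon guidance ligand (13.4-fold, chromosome 11, 35429143 to 35476438), intergenic ones named for Actr2 (12.2-fold), Spred2 (11.8-fold) and Spag9 (11.7-fold), all on chromosome 11, and one named for Efna5 (10.4-fold, chromosome 17, 62109482 to 62112841). Of the 10 highest transcripts with a TKO-only region, not all named here, 6 lay on chromosome 11. A pair of intergenic transcripts on opposite strands near Crabp1, which encodes a retinoic acid binding protein, was 10.0-fold and 9.81-fold higher in the authors' deposited table. Lower transcripts with a WT-only region included Rab11fip5, an effector of Rab11, at a log2 value of -1.78. The table describes these libraries, as transcripts are not replicates. Where a replicate was left out, the regions of its genotype came from the list left alone. In Fisher's exact tests, the odds ratio was 4.02 without chromosome 11 (p = 0.00093), 1.89 without TKO replicate 2 (p = 0.025), 3.03 without TKO replicate 1 (p = 8.7e-08) and 2.52 with a replicate block, and in the crossed split of the libraries it was 0.71 (p = 0.52).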

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

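The settings without chromosomes or a part of one were chosen after the data had been seen, as were the count with regions as units and the test of intergenic against gene transcripts; the other settings were planned. Of 146 alternative values, 121 kept their direction and their side of the threshold or moved little, 23 moved and 2 reversed. The limits behind the 121 were wide. The ratio of RNH to control peaks counted as little moved at 13.7 against 21.7. Values without a test were judged by sign alone, so a log2 peak number of 1.06 against 0.08 counted as kept. Merging transcripts, which changed nothing, is also among the 121. The exact tests of 2 against 2 libraries cannot pass 0.05, so staying on the same side says little for peak number, promoters and folds between genotypes. The odds ratio of transcript direction against genotype-only regions stayed above 1 in its 12 alternatives (1.89 to 7.22). Among these, keeping control peaks and leaving out chromosome 14 from 90 to 100 Mb left every count unchanged, so they add nothing. The odds ratio of intergenic against gene transcripts lay between 3.43 and 3.53 in 5 alternatives. Without a library, the odds ratio alone was tested.

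Peak number (log2 TKO over WT) ranged from -0.91 to 1.06 when single libraries were left out, and reversed without TKO replicate 1 (-0.91) and WT replicate 2 (-0.80). Replicate 1 has the longer list in both genotypes, so this follows from leaving out a library. Without single libraries, TKO-only regions ranged from 517 to 10239 and WT-only regions from 597 to 7214. Their ratio, 0.966 with all libraries, ranged from 0.0717 to 17.2. Here the whole list of the library left stood in for the regions of both replicates of its genotype. These values therefore do not measure the same thing as those with all libraries. The stricter threshold gave 147 and 214 regions, a ratio of 0.687, with fewer peaks tested. Equal list lengths gave 263 TKO-only regions and a ratio of 0.835, and leaving out chromosome 11 gave 0.838 and leaving out chromosome 14 from 90 to 100 Mb gave 1.11. The fold of peaks in higher transcripts was 1.85 with an overlap of 50% and 1.55 when shuffled within gene bodies, where the fold in lower transcripts was 0.996. Without chromosome 11, 57.1% of transcripts were higher, and 57.9% without chromosomes 1, 11 and 14. The number of list tests passed was 14 with peaks in either replicate, including all 8 found before (in 1 of them, lower H1 genes, the direction was fixed by the choice of sign). That setting changes the tests on transcripts, among them those of H1 and germline genes, through the adjustment alone. Without chromosomes 1, 11 and 14 the number was 5, where fewer genes were tested. Beyond what is stated, the cause was not tested.

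With a replicate block, the ratio of genotype-only regions was 1.15, the odds ratio 2.52, the log2 peak number 0.08 (exact sign-flip test, p = 1) and the promoter difference 6.03 points (exact p = 0.5, the smallest possible). Deviations of the replicates correlated at r = 0.0467 over 36099 regions, a measure that removes any shift common to all regions. Such a shift was present: replicate 1 had 25392 and 22336 peaks in TKO and WT, replicate 2 had 6458 and 6612. Whether the replicate numbers pair the libraries therefore cannot be told, and 2 pairs can show little. The stricter threshold left 0 lower transcripts with a TKO-only region and so no odds ratio, equal lengths fix the peak number, and no transcripts on one strand overlapped, so that merging changed nothing. Depth is unknown, so a peak missing from a list cannot be read as absent.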

Other observations

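The use of 3 tests to weigh explanations of transcript direction against MapR regions was chosen after their results were seen, although equal list lengths was a planned setting. Also chosen then were the neighbour test, the genes with many transcripts and the long non-coding RNA genes described here. Several genes were surrounded by transcripts that all went one way. In the authors' deposited table Bcat1, an enzyme of branched-chain amino acid breakdown, had 14 transcripts outside the gene class named for it, all higher in TKO, over chromosome 6 from 144671352 to 145103122, with log2 values up to 7.42. Its neighbour Sox5, a transcription factor gene, had 10, all higher. Bcl11a, a zinc finger repressor on chromosome 11, had 9, all higher, up to 8.15, and Ndn, an imprinted gene on chromosome 7, had 6, all higher, up to 4.65. On the X chromosome 8 of 9 near Slitrk2 were lower, and all 6 near Adgrl2 on chromosome 3 were. An intergenic transcript usually shared the direction of the listed gene transcripts within 100 kb or of its name: of those with neighbours of one direction, 357 higher ones had higher and 121 lower neighbours, while 17 lower ones had higher and 205 lower neighbours (Fisher's exact test, odds ratio 35.6, p = 4.7e-68). This test takes transcripts as independent units, although several can share a neighbour, and chromosome 11 was included.

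Annotated long non-coding RNA genes lying at least 50% inside transcripts outside the gene class numbered 301, of which 225 (74.8%) were in higher and 76 in lower transcripts. This was near the 75.6% of all transcripts outside the gene class, 2130 of 2819. All 6 Platr genes among them, named for pluripotency-associated transcripts, lay in higher transcripts, with log2 values from 1.51 for Platr11 to 1.99 for Platr14. Ftx, a gene of the X-inactivation centre (-1.83), Pvt1 (-1.42) and Halr1 (-1.30) lay in lower ones.

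Chromosome 11 was shifted toward TKO in transcripts and in MapR peaks. A few loci did not account for it, since the odds ratio was 4.92 without its 3 fullest 10-Mb bins, nor did gene density, with Spearman's rho of 0.0596 over 19 other chromosomes (permutation p = 0.80). One more copy of the whole chromosome in the TKO line is a candidate explanation: 92.3% of its bins (12 of 13) had a larger share of higher transcripts than the other chromosomes, and TKO held the larger share of MapR peaks in both replicates in 13 of 13 bins. Each listed transcript changed at least 2.00-fold, more than an added copy gives by dose alone. Such a copy could therefore not be the whole account of these changes. Any other shift of the whole chromosome would pass the same counts of bins. DNA copy number was not measured here, and an effect of H1 loss on this chromosome stays open as untested.

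Among the few transcripts with one kind of genotype-only MapR region, transcript direction and region went together, with an odds ratio of 5.22. Copy number of chromosomes 1, 11 and 14 was not the whole cause, as it was 4.02 without them. Unequal list lengths were not either, as it was 7.22 with equal lengths. Copy number elsewhere was not tested. Of 273 bins of 10 Mb, 3 held at most 0.5 times the WT share of peaks in TKO in both replicates, and 0 at least 2 times. Of the 3, only chromosome 14 from 90 to 100 Mb lies on the chromosomes left out. The 3 ways to pair the 4 RNH libraries are too few for a share under 0.05; 1 of them, the real one, reached 5.22, and the highest of the others, taken as odds ratio or inverse, was 1.42. More RNA at a site may give more R-loops, a hypothesis that was not tested.

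Transcripts outside the gene class were mostly higher in TKO. The shift of chromosome 11 was not the whole cause, as the odds ratio of intergenic against gene transcripts was 3.53 without it, nor was shorter width, with a pooled odds ratio of 2.85 over groups of like width (95% interval 2.50 to 3.25). Transcription that runs on from higher genes, or spreads around them, may account for part: 26.0% of higher intergenic transcripts (373 of 1434) were named for a gene with a higher gene transcript or had one within 100 kb. The like share was larger on the lower side, where 41.6% of lower intergenic transcripts (209 of 503) had such a lower gene. The 26.0% alone therefore does not show why most were higher. Whether such transcription accounts for more cannot be told apart, because genes that rose less than 2-fold are not listed. Loss of H1 itself stays open as untested, with 1 line per genotype.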
